A study of Caenorhabditis elegans with 2 samples.

How the data were processed

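Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult Caenorhabditis elegans in which the gene K11D2.4 had been tagged at its own locus with eGFP and further epitope tags by CRISPR, per the labels. The labels give an antibody against GFP, an age of 62 hours after release of starved first-stage larvae, and sonicated fragments of 200 to 800 bp. They name 1 group of 2 biological replicates, replicate 1 and replicate 2. No untagged or input library was analysed here, so every background below comes from the genome, from the flanks of the peaks or from lower-ranked peaks.

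The analysis started from 8 peak lists on the genome build ce11, per the labels. The authors' lists are named as ranked and thresholded by the irreproducible discovery rate (IDR), a measure of how reproducibly a peak is ranked between replicates or between parts of 1 replicate. Each replicate had a ranked list and a thresholded list of its own, and the pooled replicates had 2 ranked and 2 thresholded lists, per the deposited notes. The aligner, the peak caller, their versions and the number of reads are not given in the sources used here, so the depth behind each peak is unknown. The deposited score of a peak is a whole number of at most 1000 read here as following the IDR ranking, and the lowest score in the main list was 830. The deposited signal of a peak is the authors' own peak height; its scaling is not given in the sources used here, and it was used to describe, rank and filter peaks within a list and to correlate the replicates across peaks. The deposited thresholded lists were derived with a further file that the ranked lists did not use, per the deposited notes. The pooled ranked lists also hold 4 columns of values per replicate with no header to say which replicate each belongs to, and these were not used. The ranked lists, of 41734 to 75164 peaks, served as backgrounds, for the correlation between replicates, to find peaks of 1 replicate alone and to find peaks absent from the main list.

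The main peak set was the pooled thresholded list named conservative. Peak summits were compared with the Ensembl annotation (release 115) of WBcel235, which has the same sequence names and lengths as ce11. It holds 19973 protein-coding genes on the 6 nuclear chromosomes. Gene symbols and products were taken from RefSeq through the WormBase gene identifier. A promoter ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start. Each summit was counted once, in the order promoter, coding exon, UTR, intron, 500 bp downstream of a gene, and intergenic. Shares were compared with genome coverage by two-sided exact binomial tests, with exact Clopper-Pearson 95% intervals, and gene lists with two-sided Fisher's exact tests over all protein-coding genes. Benjamini-Hochberg adjustment ran over the 41 lists (35 gene lists and 6 tissue marker lists), over the 6 genomic classes, over the 6 chromosomes, over the 6 small RNA gene classes, over the 2080 6-base words and over the 24 fixed patterns. Sequence words within 50 bp of the summit were compared with flanks of the same total width centred 250 bp away, by an exact McNemar test. GC content over 100 bp was compared with flanks 200 to 300 bp away. Overlap between replicates was set against 10000 rotations within chromosomes. The intervals and p-values treat peaks, or genes, as independent and cover counting error within these lists; they do not measure the spread between animals. With 1 group there was no comparison between groups.

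The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the protein-coding genes whose promoter holds one of the 20 main peaks with the highest signal among those that overlap a peak of both replicates' own thresholded lists; K11D2.4; up to 4 members with the highest promoter peak of each list past the threshold or described; and up to 5 peaks of each replicate's own list, highest by signal, that overlap no peak of the other's ranked list. Alternatives were the second pooled list, the 50% of the main peaks with the highest signal, each replicate's own list alone, other promoter windows, backgrounds, window sizes and overlap rules. In simulated data with known answers, a promoter share of 50.0% was recovered as 50.0% over 1927 peaks. That value checks the counting only, since the summits were drawn from the same promoter windows. Of 9 gene lists whose odds were raised 5 times over 19973 genes, 8 were called, and 0 of the 19 lists that share no gene with them were called. A word planted near 192 simulated summits ranked 1 of 2080 words. These summits lay at random positions, where 0 words were called without the planted word. The real centres are richer in GC than their flanks, so this rank does not show that a true word would stand out here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.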

Results

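Binding sites of K11D2.4, a gene on chromosome I from 12518787 to 12528322 (plus strand, build ce11) whose product RefSeq names a C2H2-type zinc finger domain protein, were mapped by ChIP-seq of the eGFP-tagged protein in whole young adults. The data were 2 biological replicates of 1 group. The main list held 1927 peaks, the second pooled list 1984, and the replicates' own thresholded lists 959 (replicate 1) and 1141 (replicate 2). Of the main peaks, 1618 (84.0%) had the same width of 324 bp. The authors' signal ranged from 2.24 to 1396 in the main list, with a median of 101.

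The highest peaks shared by both replicates lay in promoters, those of ribosomal protein genes among them, and at sites away from promoters. The highest was at III:3867394-3867731 with a signal of 1396, its summit at -281 bp from the start of rpl-3, which encodes a protein of the large ribosomal subunit. Of the 20 highest peaks found in both replicates' own lists, 11 lay in a promoter. These promoters included the ribosomal protein genes rpl-18A (signal 868, shared with the divergent gene Y17G9B.5), rpl-15 (810, shared with K11H12.8) and rpl-35 (797). They also included tasp-1, a taspase homologue (1197, with K01G5.10 on the other side), rpa-2, a subunit of replication protein A (846), cdc-48.1, an AAA ATPase of protein degradation (810.0), and mog-4, an RNA helicase of splicing (798). A single peak of signal 768 lay between the divergent heat shock genes F44E5.4 and F44E5.5. The remaining promoters were those of nspc-17 (844) and fbxb-58 (699), both on X. The other 9 peaks had no promoter within range, and 5 of them were on X. The highest of these were at IV:4725435-4725762 (signal 1260, 460 bp past the nearest start, that of K08F11.1, and classed as downstream of a gene), IV:4727897-4728202 (1129, intergenic) and X:11093933-11094398 (918, intergenic).

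The replicates were compared by the peaks they shared. Of replicate 1's own peaks, 680 of 959 (70.9%, exact 95% interval 67.9 to 73.8) overlapped a replicate 2 peak, and 675 of 1141 replicate 2 peaks (59.2%, 56.2 to 62.0) overlapped a replicate 1 peak. Rotation of the peaks within chromosomes gave means of 0.628% and 0.516%, and the one-sided permutation p was 0.0001 in both directions, the smallest that 10000 rotations can give. Of the main peaks, 705 (36.6%) overlapped a peak of both replicates' own lists and 696 (36.1%) overlapped neither, while 1904 overlapped a ranked peak of both. Across those 1904 peaks, which are not independent replicates, the Spearman correlation of the signals was 0.653 and the Pearson correlation of log2 signals was 0.843. The SD of the log2 ratio of replicate 1 to replicate 2 was 0.41. The main peaks were selected by IDR, a measure of reproducible ranking, so some of this agreement may be built in by the selection. Only 18 replicate 1 peaks (1.88%) and 37 replicate 2 peaks (3.24%) overlapped no peak of the other replicate's ranked list. The highest of these were at II:3076991-3077286 in replicate 1 (signal 125, nearest to Y25C1A.8) and at III:8043866-8044078 in replicate 2 (signal 235.3, nearest to K12H4.5).

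**Figure D1:**
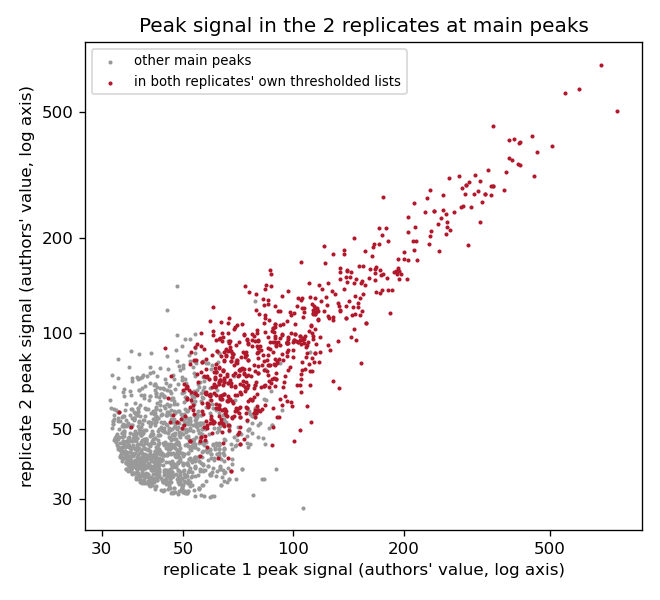
The authors' peak signal in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, at each main peak with a ranked peak in both replicates. Each point is 1 of 1904 peaks; the 705 found in both replicates' own thresholded lists are red and reach the highest signals.

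The tagged gene itself held 1 main peak, at I:12524421-12524744, with a signal of 157 and rank 402. Its summit, at 12524583, lay in an intron and at -925 bp from an internal transcript start at 12525508, so it counted as a promoter peak of K11D2.4 itself. Replicate 1's own list had 1 peak there (signal 84.7, rank 345) and replicate 2's own list also had 1 (82.6, rank 393).

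Promoters held 996 of the 1927 main summits (51.7%, exact 95% interval 49.4 to 53.9), against 26.1% of the genome (ratio 1.98, exact binomial adjusted p = 1.16e-124). Coding exons held 5.76% of summits and 18.96% of the genome (adjusted p = 9.80e-63, exact binomial test), and introns 15.5% against 27.1% (adjusted p = 1.03e-33, exact binomial test). The 500 bp downstream of genes held 5.97% against 3.51% (adjusted p = 1.20e-07, exact binomial test). Intergenic sequence held 19.4% against 21.6% (adjusted p = 0.0215, exact binomial test) and UTRs 1.71% against 2.73% (adjusted p = 0.00496, exact binomial test). The intergenic direction depended on the background. With ranked peaks in place of genome bases, intergenic sequence held more summits (19.4% against 17.3%, ratio 1.12, Fisher's exact adjusted p = 0.0174). The other classes kept their direction. The median promoter summit lay at -216.5 bp from the nearest start (interquartile range -419 to -78.8), and 43.5% of all summits were within 500 bp of a start. Promoters between divergent genes whose starts were within 2000 bp held 265 of the 996 promoter peaks (26.6%, 23.9 to 29.5), against 8.63% of promoter bases (ratio 3.08, exact binomial p = 3.60e-62). Only bases between the 2 starts counted as divergent, while promoter bases also include 200 bp downstream of each start. Of promoter summits, 86.2% lay upstream of the nearest start, so a preference for upstream sequence may raise this ratio.

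**Figure D2:**
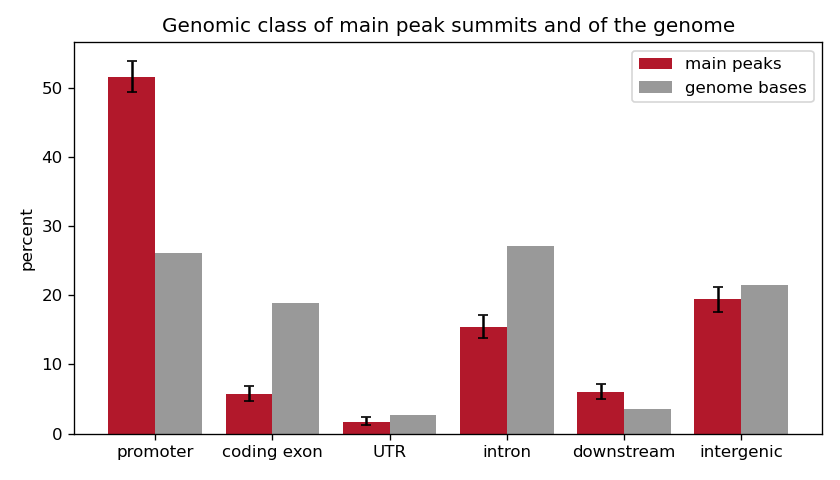
Percent of the 1927 main summits in each genomic class (red, bars with exact 95% intervals) and percent of genome bases in that class (grey). Promoters held 51.7% of summits and 26.1% of bases.

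Promoter peaks marked 1152 protein-coding genes (5.77% of 19973). Ribosomal protein, chaperone, mitochondrial respiration and chromatin genes carried promoter peaks more often than other genes. Of 78 ribosomal protein genes, 33 had a promoter peak (42.3% against 5.62% of other genes; odds ratio 12.3, 95% interval 7.57 to 19.8; Fisher's exact adjusted p = 1.51e-19). Chaperone genes had one in 18 of 62 cases (odds ratio 6.77, 3.67 to 12.01), led by cct-8 of the cytosolic chaperonin (signal 624), the mitochondrial chaperonin gene hsp-60 (457), dnj-13 (385) and hsp-1 (374). The cct-8 and hsp-60 peaks, at -442 and -621 bp, lay nearer to the starts of Y55F3AR.2 (-179 bp) and Y22D7AL.10 (-192 bp). Genes of mitochondrial respiration had one in 12 of 42 cases (odds ratio 6.59, 3.07 to 13.3), with cox-5A (604), cox-5B (272) and cox-6B (223) of cytochrome c oxidase and atp-1 (297) of ATP synthase highest; the cox-6B peak lay nearer to Y71H2AM.20. Of 106 chromatin genes, 27 had a promoter peak (odds ratio 5.69, 3.52 to 8.95), with the highest peaks at the histone methyltransferase gene set-16 (565), the acetyltransferase gene cbp-1 (506), set-21 (483) and lin-54 (433). The set-16 peak lay at -174 bp from set-16 and -172 bp from drr-2, and the set-21 and lin-54 peaks lay nearer to the ribosomal protein genes rpl-7A (-71 bp) and rpl-12 (-32 bp) and counted in both lists. The Fisher's exact adjusted p was 7.36e-08 for chaperones, 1.93e-05 for respiration and 5.15e-10 for chromatin. With each peak given to the gene of the nearest transcript start, the chaperone call was lost (odds ratio 1.88, Fisher's exact adjusted p = 0.251, over a range of odds ratios of 1.88 to 10.01 across 10 alternatives), and the odds ratio was 5.35 for ribosomal protein and 2.99 for respiration genes, with 7.28 for ribosomal protein genes against genes with a ranked peak. Without an untagged library, unspecific precipitation at highly transcribed genes was not tested for any of these lists.

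Further lists passed the same test at lower odds. Splicing and RNA processing genes had a promoter peak in 11 of 48 cases (odds ratio 4.89, 2.25 to 9.83), among them prp-19 (signal 290), snr-4 (199) and the divergent pair rsp-1 and rsp-2, which share 1 peak (205). The splicing odds ratio was 8.88 in replicate 2's own list. The list of nucleolar and snoRNP names, which also takes in whole gar, larp and wdr name series, had one in 8 of 37 (odds ratio 4.53, 1.79 to 10.2). Its highest members were larp-1, a La-related protein (306), pro-1 of rRNA processing (184), fib-1, the fibrillarin gene (158), and wdr-23, a homologue of a ubiquitin ligase adaptor (113), so the count is not one of nucleolar genes alone. Cytoskeletal genes had one in 12 of 61 (odds ratio 4.03, 1.95 to 7.72), led by wve-1 (331), the tubulin genes tba-2 (232) and tbb-1 (131), and klc-1 (190). Translation factor genes had one in 11 of 60 (odds ratio 3.69, 1.73 to 7.22), with iff-2 (431) and the elongation factor genes eef-1G (220), eef-2 (217) and eef-1A.2 (200) highest. Cell cycle and replication genes had one in 11 of 72 (odds ratio 2.96, 1.40 to 5.70), among them rpa-2, cdc-48.1, pcn-1 (274) and knl-3 (201). Genes of RNA polymerase and general transcription had one in 10 of 69 (odds ratio 2.78, 1.27 to 5.51), among them rpb-11 (247), mdt-26 (223), mdt-6 (148) and cdk-7 (146). Among other named transcription factors, 20 of 164 had one (odds ratio 2.29, 1.35 to 3.69), with ztf-7 (361), daf-16 (224), zfp-3 (205) and cebp-1 (193) highest. Several of these peaks lay nearer to the start of another gene. They were those of prp-19 (-637 bp, against -38 bp for K10D2.5), larp-1 (-656 against -333 for wip-1), mdt-6 (-912 against 6 for Y57E12AL.1), knl-3 (-419 against -223 for T10B5.3), wve-1 (-635 against -614 for R06C1.4) and tbb-1 (-226 against -152 for rib-2). The Fisher's exact adjusted p was 0.000412 for splicing, 0.00384 for the nucleolar list, 0.000824 for cytoskeletal, 0.00257 for translation factor, 0.00777 for cell cycle, 0.0153 for RNA polymerase and 0.00640 for the other factor genes. The cell cycle call was kept in 5 of 10 alternatives and lost with each replicate's own list alone (odds ratios 2.14 for replicate 1 and 1.76 for replicate 2), with the 50% of peaks with the highest signal (1.98), with the nearest transcript start (2.29) and with peaks in both replicates' own lists (2.18). Lost too were the nucleolar and cytoskeletal calls with replicate 1's own list (3.47 and 3.13). With peaks in both replicates' own lists, an alternative chosen after seeing the data, the nucleolar odds ratio was 2.11 (Fisher's exact adjusted p = 0.419, over a range of odds ratios of 2.11 to 5.20) and the cytoskeletal call was lost too (3.32), as it was with the 50% of peaks with the highest signal (2.90). The RNA polymerase call was kept in 5 of 10 alternatives and lost with the second pooled list (2.38), and that of the other factors was lost with the narrower promoter (1.92).

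Chemoreceptor, immunity and F-box genes carried promoter peaks less often than other genes. Of 1232 chemoreceptor genes 6 had one (0.487% against 6.11% of other genes; odds ratio 0.0751, 0.0275 to 0.165; Fisher's exact adjusted p = 3.83e-23), with sri-5 (signal 259), srh-269 (201), srh-2 (172) and srh-16 (139) highest; the odds ratio was 0.187 with the nearest transcript start. Of 351 immunity and C-type lectin genes 1 had one, clec-126 (98.8; odds ratio 0.0459, Fisher's exact adjusted p = 3.31e-07), with an odds ratio of 0.161 in replicate 1's own list and 0 in that of replicate 2. F-box genes had one in 6 of 322 cases (odds ratio 0.307, Fisher's exact adjusted p = 0.00384), led by fbxb-58 and fbxb-85 (244). The lists for neuropeptides (1 of 151, ins-39, signal 508), detoxification (4 of 223, dhs-8 highest at 168) and synaptic and ion channel genes (5 of 246, lev-9 highest at 155) also passed, at odds ratios of 0.108, 0.296 and 0.336 (Fisher's exact adjusted p = 0.00754, 0.0153 and 0.0198), and each of these 3 calls was lost with either replicate's own list alone. The odds ratios for neuropeptides, detoxification and synaptic genes were then 0.189, 0.518 and 0.349 with replicate 1 and 0.156, 0.428 and 0.387 with replicate 2. With the nearest transcript start they were 0.431 for neuropeptides and 0.761 for synaptic genes (Fisher's exact adjusted p = 0.140 and 0.549), and the synaptic and detoxification calls were also lost with the second pooled list (0.596 and 0.433). Of 10 alternatives, the call was kept in 4 for neuropeptides, 4 for detoxification and 3 for synaptic genes. The F-box call was lost against genes with a ranked peak in the promoter (0.449) and with peaks in both replicates' own lists (0.228), and its odds ratio was 0.136 with the narrower promoter. No tissue marker list passed, and none had an unadjusted p under 0.05 in Fisher's exact test. Germline and oocyte markers had a promoter peak in 0 of 31 genes (upper odds ratio limit 2.06, Fisher's exact adjusted p = 0.393), and neuronal markers in 1 of 21, ric-4 (85.6). Of the 41 lists, 19 had an unadjusted p under 0.05 and 17 passed adjusted 0.05, 11 of them above and 6 below an odds ratio of 1.

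**Figure D3:**
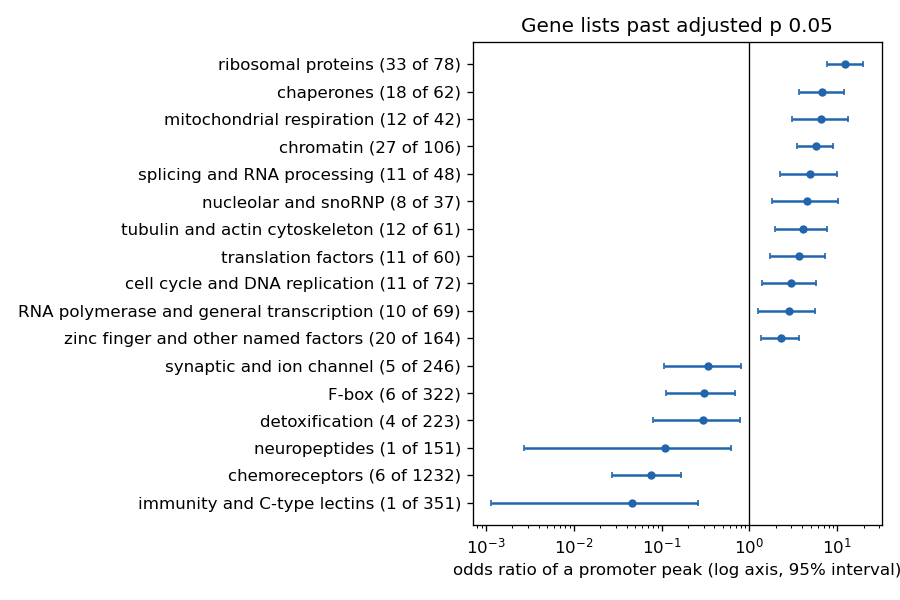
Odds ratio of a promoter peak (log axis) with its 95% interval for each gene list past an adjusted p of 0.05, with the number of its genes that had a promoter peak. Ribosomal protein genes had the highest odds ratio (12.3) and immunity and C-type lectin genes the lowest (0.0459).

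Summits lay near genes for tRNAs, for the snRNAs of splicing and for the snoRNAs that guide RNA modification. Within 200 bp of a tRNA gene lay 145 main summits (7.52%, exact 95% interval 6.39 to 8.79), against 0.272% of the genome (ratio 27.6, exact binomial adjusted p = 5.89e-152), and 155 of 612 tRNA genes had a summit that near. The ratio was 17.4 for snRNA genes (22 summits, exact binomial adjusted p = 8.14e-20), 17.1 for snoRNA genes (60 summits, exact binomial adjusted p = 2.30e-51) and 5.73 for miRNA genes (13 summits, exact binomial adjusted p = 9.70e-07). The miRNA call was lost with either replicate's own list alone (0.313% and 0.351% of peaks). Genes for 21U piRNAs had fewer summits than their share of the genome (18 summits, 0.934% against 3.32%, exact binomial adjusted p = 2.05e-11), and rRNA genes had 0 summits, which allows up to 0.191% of peaks. That count rests on the main list, since 2 ranked peaks with a score of 1000 that are absent from it overlapped the rRNA genes rrn-4.7 (signal 153) and rrn-4.6 (149).

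Summits were spread unevenly over the chromosomes (chi-square 56.9, p = 5.24e-11, chi-square test of counts against length). X held 433 summits (22.5%, exact 95% interval 20.6 to 24.4) against 17.7% of the genome (exact binomial p = 8.56e-08, adjusted over the 6 chromosomes 5.14e-07). III held 1.15 times its share, IV 0.845 times and V 0.791 times (exact binomial adjusted p = 0.0134, 0.00322 and 4.17e-06). Set against the lower-ranked peaks in place of chromosome length, the X share was no longer called (20.8% of 69974 ranked peaks outside all thresholded lists, Fisher's exact p = 0.0781); this background was chosen after seeing the data. On the autosomes 60.8% of summits lay in the central 50% of the chromosome length (exact binomial p = 4.90e-17), and on X 45.03% (exact binomial p = 0.0434), a call on X that was lost with replicate 2's own list (44.7%, exact binomial p = 0.105) and with the second pooled list (exact binomial p = 0.0505).

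Peak centres were rich in GC and in many words that hold G and C. The median GC content of the central 100 bp was 48%, against 35.5% in the flanks and 35% at random positions, and it exceeded the flanks at 1642 peaks and fell below them at 264 (exact binomial sign test p = 1.01e-242). Of 2080 6-base words, 627 were more frequent at the centre and 429 less frequent. The words with the smallest p were AT-rich and rarer at the centre, TTAAAA first (6.64% of centres against 27.7% of flanks). The first of the words more frequent at the centre was CGCAGA (13.2% against 2.23%, ratio 5.93, exact McNemar adjusted p = 2.40e-37), followed by the overlapping ACGCAG. Among patterns fixed before the data were examined, AGACGCAG (read as CTGCGTCT on the other strand) was at 154 centres and in 17 flanks (ratio 9.06, exact McNemar adjusted p = 8.31e-29), GAGAGA at 429 and 152 (ratio 2.82, exact McNemar adjusted p = 5.31e-35), GCGCGC at 139 and 23 (ratio 6.04, exact McNemar adjusted p = 2.24e-21), CCCGCCC at 44 and 4, and the E-box CACGTG at 108 and 40. In replicate 2's own list the ratio was 22 for AGACGCAG, 10.1 for GCGCGC and 4.56 for CACGTG. For CCCGCCC it was 11 in the main list, 17 in replicate 1's own list and 9.33 in that of replicate 2. With the second pooled list the ratio was 7.79 for AGACGCAG, 6.24 for GCGCGC, 2.89 for CACGTG and 8.17 for CCCGCCC. Within 100 bp of the summit it was 3.55 for CCCGCCC and 0.483 for TTAAAA, and GCGCGC had 13.3 in the 50% of peaks with the highest signal. Of the 24 fixed patterns, 9 passed the threshold as more frequent at centres and 7 as rarer there. The rarer ones included TTTGAA (234 centres against 524 flanks), the splice acceptor pattern TTTCAG (148 against 372), TATAAA (76 against 192) and TAATTA (27 against 86). The flanks held less GC than the centres, so base composition alone could raise GC-rich patterns at centres and lower AT-rich ones. Of the fixed patterns only AGACGCAG was set against words of its own composition, and for the others this was not tested.

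**Figure D4:**
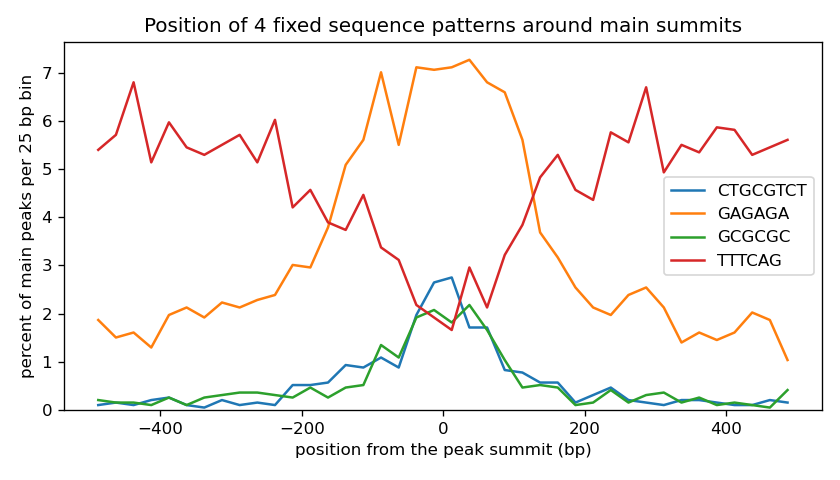
Percent of the 1927 main peaks with each of 4 fixed patterns, on either strand, in 25 bp bins (y axis) by position from the summit in bp (x axis). GAGAGA, CTGCGTCT and GCGCGC rise around the summit and TTTCAG falls there.

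Strong and weak peaks differed in where they lay. Of the 481 main peaks with the highest signal 297 (61.7%) were in promoters, against 213 (44.3%) of the 481 with the lowest (Fisher's exact p = 7.66e-08). Of the strong peaks 454 were in both replicates' own lists, against 48 of the weak peaks. No test is given, since the ranking and the lists rest on the same libraries. Main peaks were also parted into 4 groups by falling signal (482, 482, 482 and 481 peaks). Of these, 455, 189, 13 and 48 were in both replicates' own lists, so support did not fall steadily with signal. The lowest group held 65 coding exon peaks, against 6 in the highest. TTAAAA was at 27 strong and 40 weak peaks (Fisher's exact p = 0.128). CGCAGA, a word chosen after seeing the data, was at 85 and 35 (Fisher's exact p = 1.29e-06). The promoter difference of 17.5 percentage points was 8.07 in replicate 2's own list and no longer past the threshold there (Fisher's exact p = 0.0617); the CGCAGA difference of 10.4 points was 5.86 in that of replicate 1 (Fisher's exact p = 0.0761).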

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

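The lists not used for the main comparisons held 50 pooled ranked peaks whose score reached the lowest score of the main list but which were not in it. They stand out because 36 of them had a signal above the main median, and the highest, at X:15810938-15811210, had a signal of 3065, against 1396 for the highest main peak. The next were at X:293333-293507 (signal 822), X:15808108-15808278 (576) and V:5284094-5284251 (551). A pair of them overlapped the rRNA genes rrn-4.7 (153) and rrn-4.6 (149). Per the deposited notes the thresholded lists were made with a further file, not analysed here. No test of why these peaks are absent was run, before or after they were seen.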

How the results depend on the processing

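The both-replicate peaks, the peaks away from small RNA genes and the ranked peaks as background for X were chosen after seeing the data. In the alternatives run for the main results, 165 values kept their direction and side of the threshold or stayed close, 16 moved, 10 fell short of the threshold and 2 newly passed it. TTAAAA, not past the threshold in either case, changed sign between strong and weak peaks in the 50% with the highest signal. For single gene lists 38 calls were lost. The number of reads is unknown, so what depth limits could not be computed; with 2 replicates of 1 group, the alternatives of 1 replicate use that replicate's own list. With the second pooled list, the X centre share was 45.2% (exact binomial p = 0.0505) and the TTAAAA difference between strong and weak peaks -4.03 points, past the threshold. With the 50% of the peaks with the highest signal, counts fell by construction (963 peaks, 728 target genes, 3 lists called below 1); the share within 500 bp of a start was 48.3%, and the strong minus weak differences were 7.5 points for promoters, 2.92 for CGCAGA and 2.08 for TTAAAA, none past the threshold. With the peaks parted at the median signal, the TTAAAA difference was -2.49 points and past the threshold. With 8-base words 406 were more frequent at the centre. With signals from the thresholded lists the Spearman correlation was 0.776. With each replicate alone, ranges were 959 to 1141 peaks, 677 to 813 target genes, 3 to 4 lists called below 1, 47.3% to 47.3% within 500 bp, 40.8% to 44.7% for the X centre (call lost with replicate 2 alone), 0.313% to 0.351% for miRNA genes, 8.07 to 15.5 points for promoters and 5.86 to 9.47 for CGCAGA. Peaks in both replicates' own lists gave 527 target genes, 2 lists called below 1, 411 words and 0.284% at miRNA genes, and lower-ranked peaks as background ended the call on the X share of 22.5%. Beyond the smaller lists, the cause was not tested.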

Other observations

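The tests on X and the test of a joint rise of words were chosen after the result was seen. With 1 group in the design, no biological explanation was tested for the tRNA genes or for AGACGCAG.

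Lists near but not past the threshold included small RNA and germ granule genes, with a promoter peak in 7 of 53 (odds ratio 2.50, 0.948 to 5.58, Fisher's exact adjusted p = 0.0722), of which ifet-1, a translational repressor of the germline, had the highest signal (574); that peak lay nearer to the ribosomal protein gene rps-3A (-245 bp) and counted in both lists. Mitochondrial ribosome genes had one in 7 of 70 and proteasome genes in 3 of 33, with odds ratios of 1.82 and 1.64 (Fisher's exact adjusted p = 0.241 and 0.572). Histone genes had one in 4 of 72 (odds ratio 0.961), his-37 highest (signal 505). Lipid metabolism genes had one in 11 of 129 (cpt-2, 317), signalling genes in 7 of 72 (mig-5, a Dishevelled homologue, 294), body muscle genes in 5 of 49 (cap-2, 362), ubiquitin conjugation genes in 5 of 53 (ubc-6, 302.0) and nuclear hormone receptor genes in 13 of 274 (nhr-255, 214). Collagen genes had one in 4 of 178 (odds ratio 0.373, Fisher's exact adjusted p = 0.108) and homeobox genes in 1 of 92 (ceh-38). None of these lists passed. The 4 of 43 coelomocyte and excretory markers with a promoter peak were subunits of the vacuolar proton ATPase, vha-12 (168), vha-8 (144, nearer to C17H12.2), vha-13 (94.5) and vha-1 (89.1). Of the main peaks, 161 (8.35%) had central 31 bases that occur again in the genome; the share was 16.8% among strong peaks outside promoters and 5.05% among strong promoter peaks.

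Peaks at tRNA genes could come from reads shared between identical copies. Single-copy tRNA genes, those whose full sequence occurs once in the genome, argue against identical copies as the whole cause. Summits near them were 16.2 times their genome share (exact binomial p = 4.98e-17). Identical copies stay open as a part of the cause, as 23 of 140 single-copy genes (16.4%) had a peak against 132 of 472 multi-copy genes (28.0%, Fisher's exact p = 0.00559). Genes that differ from another by a few bases count as single-copy, so reads shared between near-identical genes were not tested. The GC content of the windows as the whole cause is argued against too. A summit lay in 0.999% of GC-matched windows, against 24.2% of tRNA windows. GC content stays open as a part of the cause, as tRNA windows with a summit had a higher median GC content than those without. The matching used the GC content of whole windows, so GC-rich stretches within them were not tested. Open chromatin and unspecific precipitation stay open, as no untagged library was analysed here.

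AGACGCAG at peak centres may reflect their GC content. Among 359 other words of its composition that hold a CG, its ratio was at the 96.7th percentile, between the bounds set beforehand, so this cannot be told apart; 10 of the 12 words with a higher ratio were at 77 centres or fewer, and the others, GAGACGCA and AGAGACGC, overlap AGACGCAG and are no independent comparison. An even rise of all those words is argued against by their joint ratio of 2.37. It divides the peaks with a word only at the centre by those with it only in the flanks, each summed over the words. A peak can count for several words. The joint ratio lay below the interval of the ratio for AGACGCAG alone (152 to 15, or 10.1, exact interval 5.95 to 18.6). Loci repeated exactly at their centre are argued against, with a ratio of 9.25 over the 1766 peaks whose central 31 bases occur once. Diverged copies of a repeat were not left out by this rule and were not tested. Whether K11D2.4 binds the word itself, or a site beside it, stays open as a hypothesis.

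The excess of peaks on X may be a bias of the whole chromosome, since X also held 20.8% of lower-ranked peaks, within the interval of its share of main peaks. A second hypothesis came from strong X peaks away from promoters, such as one at -4874 bp from the start of xol-1, the switch gene of sex determination and dosage compensation (signal 606). TCGCGCAGGGA, a motif of X recruitment sites of the dosage compensation complex, was present with at most 2 mismatches at 30 of 433 X peaks and 47 of 1494 autosomal peaks (odds ratio 2.29, Fisher's exact p = 0.00113), among them the X peaks of ranks 5, 8, 13, 14, 17 and 19, though X holds 16.6% of its genome occurrences. The peaks that held the motif at this setting did not make up the whole excess. Without them X kept 21.8% of the peaks (exact interval 19.9 to 23.7), against 17.7% of the genome. Their removal cannot decide whether recruitment sites caused the whole excess, since sites with a more diverged or more distant motif would stay in. Whether the strong X peaks with the motif reflect the tagged protein or unspecific precipitation stays open.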
